A study of Mus musculus with 6 samples.

How the data were processed

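RNA was measured by bulk sequencing in microglia, the resident macrophages of the brain, sorted by flow cytometry from 3xTg-AD mice, a strain that carries Alzheimer's disease-linked human APP and MAPT transgenes. Mice were 7 months old and received 25 µg of a depleting antibody against NK1.1, a surface receptor of natural killer (NK) cells, or an isotype control antibody, every 4 days for 4 weeks. Each group had 3 libraries, numbered 1 to 3 in the labels. Per the labels' protocols, total RNA was extracted with Trizol-LS, cDNA was made with the SMART-seq v4 kit, libraries were made with Nextera XT, and 75 bp single-end reads were sequenced on a NextSeq 500. These kits add no molecular identifiers and do not mark the strand of a transcript, so counting intervals cover counting error alone and reads from overlapping antisense genes such as Xist and Tsix cannot be told apart. The labels do not say whether each library came from 1 animal or from a pool, so the p-values of the gene tests measure the spread between these libraries.

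Per the submitters' processing notes, the tools were bcl2fastq 2.20.0.422, FastQC 1.0.0, STAR 2.5.3a, Cufflinks 2.0 and DESeq2 1.1, with the mouse build mm10. The counting program, the annotation and the strand setting are not given in the sources used here. The deposited table is described as normalized, but its values are read counts per gene: they are whole numbers, they sum to different totals per library, and the table holds rows for reads in no feature and for ambiguous reads. The histogram of low counts was smooth in every library, so no scaling and rounding of the deposited counts was visible. The table has 24956 gene rows. Another 26 rows carry a calendar date in place of the gene symbol and of the value for isotype 2, and were left out, and the 2 rows of total reads were kept out of library sizes and tests. Reads in no feature were 53.3% to 57.4% of all reads in the table.

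The design fixed before the data were examined assumed normalized values and foresaw a count test if the table held counts, and that count test was used. Genes were filtered with edgeR's filterByExpr, leaving 14520, scaled with trimmed mean of M values (TMM) factors, and tested two-sided with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, group as the only term, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Values per library are CPM, counts scaled to a common library size with the TMM factors. The standard error (SE) of a log2 change is its absolute value divided by the square root of F. Changes are anti-NK1.1 against isotype. Gene lists (microglial states, interferon, antigen presentation, cytokines, phagocytosis, metabolism and the other cell types a microglial sort could hold) were written before the data were examined. Each list with at least 3 tested genes was tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with adjustment over 29 lists. With the preset correlation, camera judges a list against the other tested genes, with degrees of freedom from the number of genes. Those p-values therefore do not measure how far a list as a whole varies between libraries. The test was repeated with the correlation estimated per list, where the degrees of freedom come from the libraries. It was also repeated with fry, which tests whether the genes of a list move, on balance, one way.

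Genes are named by a rule written before the data were examined. It takes the 10 genes with the largest increase and the 10 with the largest decrease past the threshold whose groups do not overlap, filled up by smallest p where fewer pass. It adds up to 3 genes of smallest p from each list, and Klrb1c, Ncr1, P2ry12, Tmem119, Cx3cr1, Trem2, Apoe, Il1b, Tnf, Il18, Cst7, B2m, App and Mapt whatever their values. Some genes that the rule takes are not reported here. Predicted loci, pseudogenes and small RNA genes are not named. Other genes named from a list were chosen after their values were seen. Coordinates are those of the GENCODE annotation of GRCm38, the assembly also called mm10, matched by symbol. Transcript length and GC content came from the same annotation for 99.1% of the tested genes.

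Library totals over genes ranged from 26.9 M to 36.1 M counts, and a floor of 3 counts corresponded to 0.0784 to 0.120 CPM. The common biological coefficient of variation was 0.640. On simulated counts with the same means and depths, the gene test recovered 2.05% of genes changed by 1 on the log2 scale, 37.1% of genes changed by 2 and 72.4% of genes changed by 4, with 16 false calls over 3 runs. No list was called in the simulated data. Genes were drawn independently there, while the estimated correlation within a list reached 0.80 in the real data. The simulation therefore cannot show how often correlated lists are called falsely. For single genes an exact permutation test of 3 against 3 libraries cannot go below p = 0.1. Pairs of libraries within a group correlated at r = 0.846 to 0.892 and pairs across groups at r = 0.796 to 0.904, so the groups did not separate by correlation. On the first principal component of log2 CPM, the axis of largest spread (32.9% of the variance), isotype libraries 1 to 3 lay at -100, -30.9 and -46.7. The anti-NK1.1 libraries 1 to 3 lay at 116, 5.76 and 56.2, with anti-NK1.1 2 nearest to the isotype libraries. Each library was treated as 1 replicate, which the values do not test.

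Alternatives fixed beforehand were other pseudocounts, filters, scalings and variance settings, sample weights, the replicate number as a block, each library left out in turn, other thresholds, DESeq2 1.42.0, an estimated correlation and fry. The pseudocount alternatives were meant for log values and were run with limma. Chosen after seeing the data were limma on log2 CPM, a correction of each library's trend with transcript length and GC content by natural splines with 5 degrees of freedom, a neutrophil covariate, and the removal of the libraries anti-NK1.1 1 and 3. The length and GC correction was also run with the block and without anti-NK1.1 2. Neutrophil share is the percentage of gene counts taken by Ngp, Camp, Ltf, S100a8 and S100a9. The length trend of a library is Spearman's rho, across genes, between transcript length and the log2 CPM relative to the mean of all libraries, where genes are not independent replicates. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.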

Results

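Gene expression was measured by RNA sequencing in microglia sorted from 3xTg-AD mice at 7 months of age. Of the 6 libraries, 3 came from mice given an isotype control antibody and 3 from mice given an antibody against NK1.1 that depletes NK cells. Gene counts totalled 36.1 M, 31.9 M and 35.9 M in isotype libraries 1 to 3 and 26.9 M, 31.4 M and 29.1 M in anti-NK1.1 libraries 1 to 3, with 14606 to 16210 genes detected. The comparison addresses how the microglial transcriptome differs when NK cells are depleted in this Alzheimer's disease model.

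Transcripts of NK cells were scarce in every library and lay lower after the depleting antibody. Klrb1c, which encodes NK1.1 itself (chromosome 6, 128778485 to 128789215, GRCm38), had 50, 45 and 80 counts in the isotype libraries and 0, 0 and 13 in the anti-NK1.1 libraries. Pooled over each group and scaled by depth, this was a ratio of 11.3 (95% counting interval 6.44 to 21.7), with an edgeR log2 change of -3.23 ± 1.82 (SE) and an adjusted p of 0.743. Ncr1, which encodes the NK cell receptor NKp46, had 128, 53 and 0 counts in the isotype libraries and none in the anti-NK1.1 libraries. Against a floor of 3 counts over the group, that was at least 50.7-fold lower, although 1 isotype library also had none. Nkg7 and Gzma, genes of cytotoxic granules, had log2 changes of -1.20 ± 0.47 and -2.16 ± 0.86, and Klrd1 had -0.68 ± 0.34. For Nkg7 the groups overlapped, with 51.2 CPM in anti-NK1.1 3 and 50.0 CPM in isotype 3. Of 13 tested genes of the NK cell list, 10 were lower, and the list fell with a median log2 change of -0.84 (camera adjusted p = 0.00414). The adjusted p = 0.279 with an estimated correlation, and none of the 13 genes passed over all genes or adjusted over the list alone.

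The clearest single-gene increases were in the machinery of MHC class II antigen presentation, in Apoe and in myelin-associated genes, although none passed edgeR's threshold over all genes. Cd74, the invariant chain that chaperones class II molecules (chromosome 18, 60803848 to 60812652), averaged 1837 ± 71.8 CPM in isotype and 4646 ± 742 CPM in anti-NK1.1 libraries (SD, n = 3 each). Its log2 change was 1.34 ± 0.20 and its edgeR adjusted p was 0.296. The class II chains H2-Ab1 (chromosome 17, 34257689 to 34269419), H2-Eb1 (34305867 to 34316674) and H2-Aa (34282744 to 34287823) had log2 changes of 1.54 ± 0.25, 1.45 ± 0.25 and 1.5 ± 0.27, which are 2.90, 2.74 and 2.82 times the isotype level. Apoe, the lipid carrier that marks disease-associated microglia (chromosome 7, 19696109 to 19699188), averaged 1503 ± 354 CPM and 3821 ± 616 CPM, a log2 change of 1.35 ± 0.24 (edgeR adjusted p = 0.403). Mbp, a major protein of myelin (chromosome 18, 82475146 to 82585637), averaged 155 ± 38.9 CPM and 541 ± 64.5 CPM, a log2 change of 1.80 ± 0.25 (edgeR adjusted p = 0.296). The lipocalin Apod had a log2 change of 2.12 ± 0.31, Plekhb1 of 1.53 ± 0.26 and Bcas1, a gene of the oligodendrocyte lineage, of 2.56 ± 0.46. Each of these 9 genes was higher in every anti-NK1.1 library than in every isotype library.

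Among the genes with the smallest p in the other direction were inflammatory and myeloid genes. Fn1, the extracellular matrix protein fibronectin and a gene of monocytes (chromosome 1, 71585520 to 71653200), averaged 93.7 ± 49.6 CPM in isotype and 17.6 ± 2.32 CPM in anti-NK1.1 libraries, a log2 change of -2.41 ± 0.38 (edgeR adjusted p = 0.366). Il1a, which encodes the cytokine interleukin-1 alpha (chromosome 2, 129299610 to 129309972), averaged 215 ± 35 CPM and 106 ± 16 CPM, a log2 change of -1.01 ± 0.23. Jak2, a kinase of cytokine receptors including that for interferon gamma (chromosome 19, 29251828 to 29313080), had a log2 change of -2.14 ± 0.50. The others were Adnp2 with a log2 change of -4.03 ± 0.81, Lrguk with -5.03 ± 1.1, Atad2 with -2.11 ± 0.46, Atp8b4 with -2.07 ± 0.47, St8sia4 with -1.80 ± 0.41 and Chp1 with -1.08 ± 0.24. Tube1 had 147, 103 and 114 counts against 1, 0 and 0, a pooled ratio of 306 (95% counting interval 54.5 to 12113). All 10 were lower in every anti-NK1.1 library than in every isotype library.

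**Figure D1:**
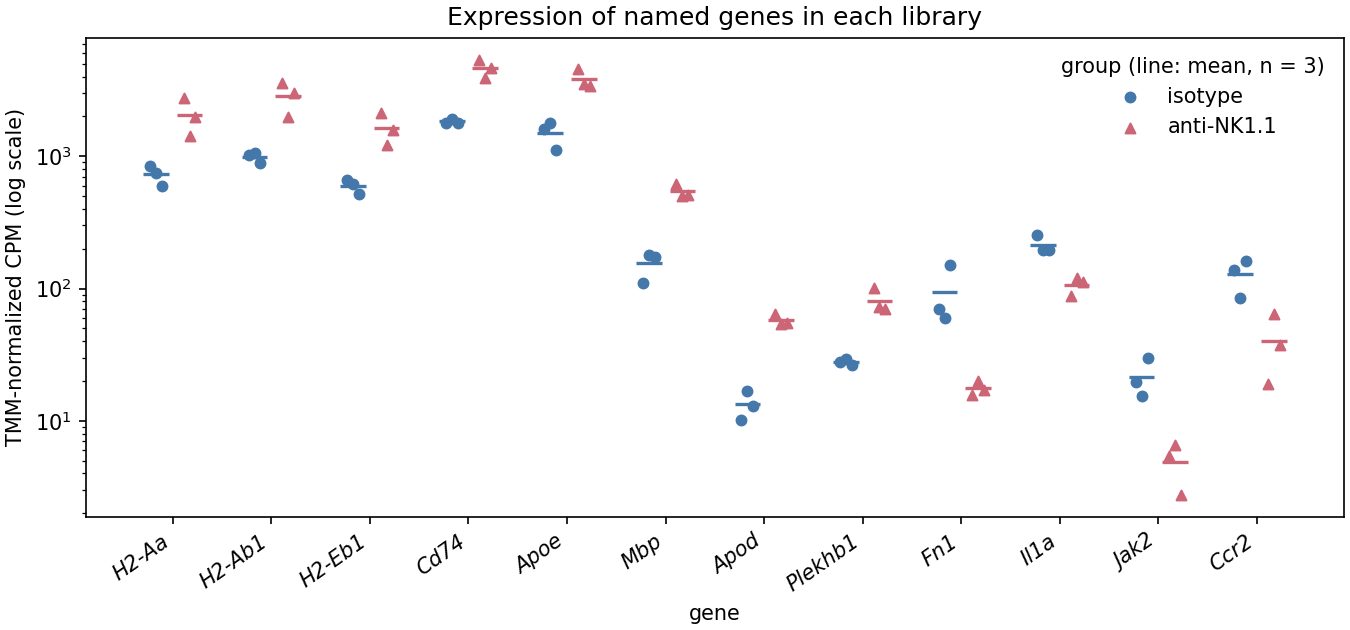
TMM-normalized CPM (log axis) of 12 named genes in each isotype library (circles) and each anti-NK1.1 library (triangles), with the group mean as a line (n = 3). The 3 anti-NK1.1 libraries lay above the 3 isotype libraries for the first 8 genes and below them for Fn1, Il1a, Jak2 and Ccr2, but none of the 12 passed edgeR's adjusted threshold.

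Over 14520 genes, edgeR's quasi-likelihood test called 0 genes at an adjusted p under 0.05, with the smallest adjusted p at 0.296. At an unadjusted p under 0.05 there were 950 genes (398 higher, 552 lower) where chance gives 726, and 2224 genes (15.3%) had groups that did not overlap, where chance gives 10%. DESeq2 called 132 genes on the same counts (76 higher, 56 lower), among them Apod, Mbp, Cd74, H2-Ab1, H2-Eb1, H2-Aa, Apoe and Fn1, and limma with quantile normalization or sample weights called 2 and 4. Leaving out anti-NK1.1 2 gave 129 edgeR calls (12 higher, 117 lower), and the 117 lower genes had a median transcript length of 5267 nt against 3272 nt for all tested genes.

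The libraries also differed in makeup within the groups. Neutrophil transcripts took 9.17%, 7.23% and 6.89% of gene counts in isotype libraries 1 to 3, and 2.87%, 3.23% and 11.1% in anti-NK1.1 libraries 1 to 3. The trend of expression with transcript length had a rho of 0.04, 0.23 and 0.54 in the isotype libraries and of -0.41, 0.38 and -0.51 in the anti-NK1.1 libraries, so long transcripts were under-represented in anti-NK1.1 1 and 3. P2ry12 and Tmem119, genes typical of microglia, were abundant in both groups, with P2ry12 at 4875 ± 277 CPM in isotype and 3254 ± 979 CPM in anti-NK1.1 libraries (SD, n = 3 each).

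**Figure D2:**
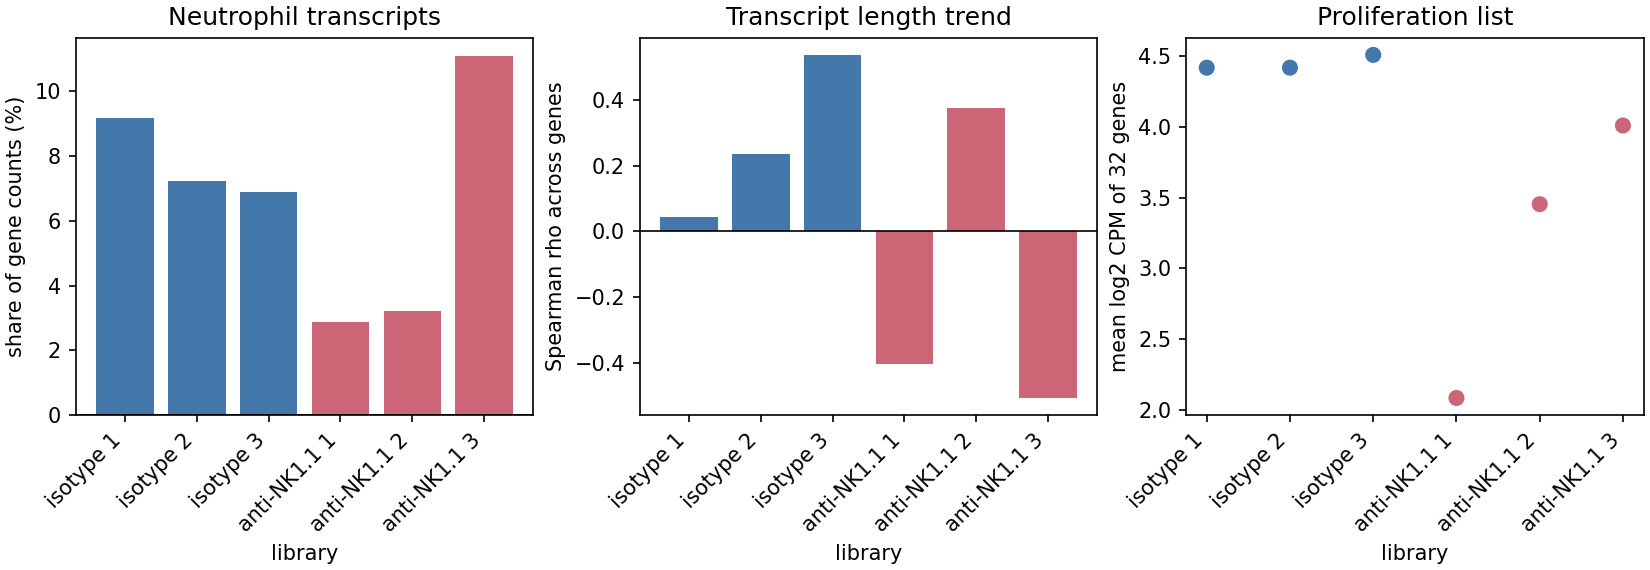
Properties of the 6 libraries (blue, isotype; red, anti-NK1.1), 1 bar or point per library. Left, the share of gene counts (%) from 5 neutrophil genes, which reached 11.1% in anti-NK1.1 3; middle, Spearman's rho across genes between transcript length and relative expression, negative in anti-NK1.1 1 and 3; right, the mean log2 CPM of 32 proliferation genes, lower in each anti-NK1.1 library than in each isotype library.

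Of 29 gene lists, 12 passed the camera threshold with the preset correlation, 8 higher and 4 lower in anti-NK1.1 libraries. None passed with an estimated correlation, and 1, the oligodendrocyte-lineage list, passed with fry (adjusted p = 0.0376). The estimated correlation reached 0.80 for ribosomal proteins. For the NK cell (-0.032), T cell (-0.019) and oligodendrocyte-lineage (-0.0078) lists it lay below the preset 0.01. A correlation above the preset thus did not end the calls of those lists. Their p-values rose because the degrees of freedom then came from the libraries and no longer from the number of genes. No member of any list passed over all genes with edgeR, while DESeq2 called members of several lists over all genes, among them 5 of antigen presentation, 5 of neurons, 3 of border macrophages and 2 each of astrocytes and of monocytes and neutrophils.

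The antigen presentation list rose with a median log2 change of 0.33, and 20 of its 23 tested genes were higher (camera adjusted p = 0.00193, adjusted p = 0.672 with an estimated correlation). Adjusted over the list alone, 6 genes passed, and all 6 belong to the class II pathway: Cd74, H2-Ab1, H2-Eb1, H2-Aa and the peptide-loading genes H2-DMb1 (0.95 ± 0.24) and H2-DMa (0.71 ± 0.23). Class I genes had smaller values, with H2-K1 at 0.55 ± 0.25, H2-D1 at 0.59 ± 0.30 and B2m at 0.32 ± 0.23, and counts of H2-K1 and H2-D1 are uncertain because class I genes share sequence. Nlrc5, the transactivator of class I genes, had a log2 change of -2.71 ± 1.23. Without anti-NK1.1 1 and 3, the list's median was 0.02 (camera adjusted p = 0.705), while the log2 changes of Cd74, H2-Ab1 and H2-Eb1 were 1.09, 1.02 and 1.02.

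Transcripts of the other resident brain cells also lay higher. The neuron list rose, with all 18 genes higher and a median log2 change of 1.5 (camera adjusted p = 3.75e-09, adjusted p = 0.316 with an estimated correlation). Its genes included the long non-coding RNA Meg3 (2.2 ± 0.52), the vesicular glutamate transporter Slc17a7 (2.85 ± 0.69) and Snhg11 (1.95 ± 0.49), and 6 passed adjusted over the list alone. The oligodendrocyte-lineage list rose, with all 15 tested genes higher and a median of 1.04 (camera adjusted p = 3.77e-05, adjusted p = 0.228 with an estimated correlation). Mbp alone passed over that list, and Mobp and Ptgds had log2 changes of 1.26 ± 0.40 and 1.04 ± 0.36. The astrocyte list rose with 10 of 15 genes higher and a median of 0.70 (camera adjusted p = 0.00360, adjusted p = 0.279 with an estimated correlation), and 2 genes, among them the carboxypeptidase Cpe (1.24 ± 0.29), passed over the list alone, while Aldoc had 1.12 ± 0.43. Without anti-NK1.1 2 the astrocyte median was 0.62 and the list no longer passed (camera adjusted p = 0.110). Levels of many of these transcripts were low: Slc17a7 averaged 1.40 CPM in isotype and 10.1 CPM in anti-NK1.1 libraries, and Cpe 36.6 CPM and 86.7 CPM.

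Border macrophage and T cell lists rose as well. In the border macrophage list 12 of 15 genes were higher, with a median log2 change of 0.86 (camera adjusted p = 0.00414, adjusted p = 0.279 with an estimated correlation). The chemokine Pf4 (1.37 ± 0.35), Ms4a7 (1.27 ± 0.33) and the lectin Cd209f (2.67 ± 0.74) were higher and F13a1, also a gene of monocytes, was lower (-1.70 ± 0.52), and these 4 passed adjusted over the list alone. Without anti-NK1.1 2 this list no longer passed (camera adjusted p = 0.140). In the T cell list 10 of 13 genes were higher, with a median of 1.03 (camera adjusted p = 0.0228, adjusted p = 0.289 with an estimated correlation). It was led by Cd3e (1.74 ± 0.76) and Cd3g (1.14 ± 0.66), CD3 subunits of the T cell receptor complex, and by Cd8b1 (1.45 ± 0.70). None of these passed over the list alone. The T cell list kept its call when isotype 2 was left out and lost it when any of the other 5 libraries was left out.

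Proliferation, myeloid and interferon gamma genes lay lower. All 32 genes of the proliferation list were lower, and the list fell with a median log2 change of -0.79 (camera adjusted p = 1.63e-08, adjusted p = 0.565 with an estimated correlation). Examples were the replication helicase subunit Mcm7 (-0.96 ± 0.32), the topoisomerase Top2a (-1.96 ± 0.66) and the kinetochore gene Cenpf (-2.11 ± 0.75), and none passed adjusted over the list alone. The monocyte and neutrophil list fell, with 17 of 20 genes lower and a median of -0.48 (camera adjusted p = 0.000119, adjusted p = 0.653 with an estimated correlation). Fn1 and the chemokine receptor Ccr2 (-1.68 ± 0.43) passed over the list alone, and Cxcr2, a neutrophil chemokine receptor, had -0.94 ± 0.30. Without anti-NK1.1 2 this list had a median of -0.18 (camera adjusted p = 0.0698). The interferon gamma response list fell, with 16 of 25 genes lower and a median of -0.54 (camera adjusted p = 0.0342, adjusted p = 0.672 with an estimated correlation). Jak2 alone passed over the list, and the guanylate-binding proteins Gbp3 and Gbp9 had -1.51 ± 0.52 and -1.47 ± 0.53. This list lost its call when isotype 3, anti-NK1.1 1 or anti-NK1.1 3 was left out (camera adjusted p = 0.195, 0.0603 and 0.124), and also with the length and GC correction (median -0.44, camera adjusted p = 0.0920).

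**Figure D3:**
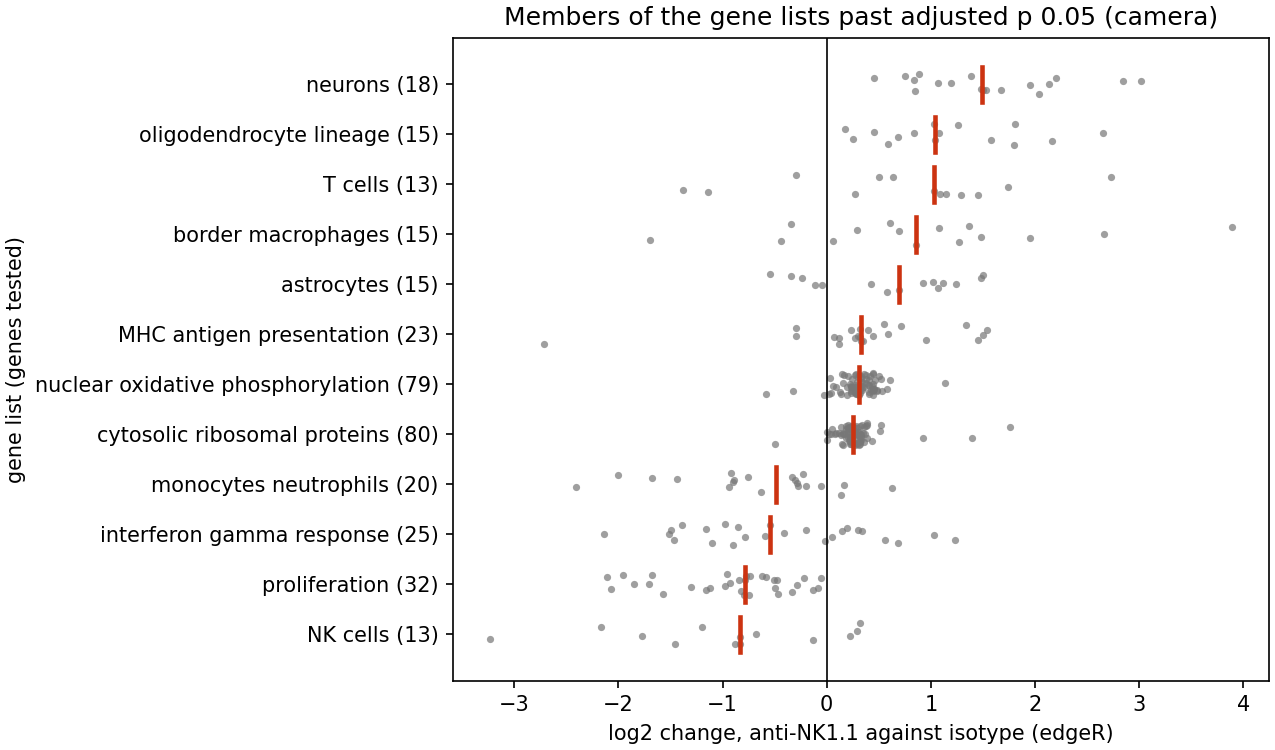
Log2 change, anti-NK1.1 against isotype, of every tested gene (grey points, 1 per gene) in the 12 gene lists past the camera threshold, with the median of each list in red and the number of genes in brackets. All 18 neuron genes and all 15 oligodendrocyte-lineage genes lay above 0, and all 32 proliferation genes lay below 0.

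The lists of short, abundant housekeeping transcripts rose by small amounts. Of 79 nuclear genes of oxidative phosphorylation, 76 were higher, with a median log2 change of 0.31 (camera adjusted p = 6.35e-05, adjusted p = 0.729 with an estimated correlation), for example Ndufa1 (0.60 ± 0.31), Ndufa13 (0.54 ± 0.29) and Cox8b (1.13 ± 0.57). Of 80 cytosolic ribosomal protein genes, 78 were higher, with a median of 0.25 (camera adjusted p = 0.00102, adjusted p = 0.729 with an estimated correlation), for example Rps19 (0.51 ± 0.26), Rps15 (0.52 ± 0.29) and Rpsa (0.39 ± 0.24). Their median transcript lengths were 1005 and 1077 nt. After correction of each library for transcript length and GC content, the oxidative phosphorylation median was 0.18 (camera adjusted p = 0.00980), and the ribosomal median was 0.0720 and no longer past the threshold (camera adjusted p = 0.437). Without anti-NK1.1 1 and 3, the ribosomal list turned to a median of -0.22 (camera adjusted p = 0.00658) and the oxidative phosphorylation list had a median of 0.03 (camera adjusted p = 0.773). Leaving out isotype 3 ended both calls (camera adjusted p = 0.435 for the ribosomal and 0.589 for the oxidative phosphorylation list), and leaving out anti-NK1.1 1 or 3 ended that of the ribosomal list (camera adjusted p = 0.280 and 0.0730).

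Lists of microglial state did not pass with the settings used for the other lists. Of 24 homeostatic microglia genes, 14 were lower, with a median log2 change of -0.07 (camera adjusted p = 0.286), and the list passed as lower with quantile normalization (median -0.16, camera adjusted p = 0.0341) and with the length and GC correction without anti-NK1.1 2 (median -0.19, camera adjusted p = 0.0186). The receptors P2ry12, P2ry13 and Tgfbr1 had -0.58 ± 0.23, -0.59 ± 0.26 and -0.98 ± 0.44, Cx3cr1 had -0.52 ± 0.36 and Tmem119 had 0.38 ± 0.24. In anti-NK1.1 2, P2ry13 (1423 CPM) and Tgfbr1 (480 CPM) lay within the isotype range and Cx3cr1 (2898 CPM) above it. P2ry12 (4384 CPM) lay below it. The falls of P2ry13, Tgfbr1 and Cx3cr1 thus came from anti-NK1.1 1 and 3, the libraries poor in long transcripts. After the length and GC correction Tgfbr1 had -0.53. Of 32 disease-associated microglia genes, 21 were higher, with a median of 0.26 (camera adjusted p = 0.326). Apoe alone passed over that list, the receptor tyrosine kinase Axl had 0.96 ± 0.30, Hif1a had -1.34 ± 0.44, Trem2 had 0.43 ± 0.31 and Cst7 had 0.42 ± 0.26. Of 40 phagocytosis and lysosome genes, 30 were higher, with a median of 0.24 (camera adjusted p = 0.117; past the threshold among genes with a mean CPM of at least 5, median 0.28, camera adjusted p = 0.0116), with Cd36 at 0.82 ± 0.33 and the integrin Itgam at -1.10 ± 0.39. In the complement list 10 of 18 genes were lower (median -0.10, camera adjusted p = 0.855), while the mean was 0.08. C1qc had 0.66 ± 0.21 and C3 had -1.56 ± 0.53.

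The cytokine and type I interferon lists did not pass with all libraries, but both passed as lower without anti-NK1.1 3 (camera adjusted p = 0.0373 and 0.00415), and the type I interferon list also without isotype 2 (camera adjusted p = 0.0392). Of 37 inflammatory cytokine and NF-kB genes, 19 were higher and 18 lower (camera adjusted p = 0.300), with a median just above 0 while the mean was -0.17 and the test pointed down. Il1a and Tnfaip3 (-1.61 ± 0.39), an inhibitor of NF-kB, passed over the list alone, Cxcl16 had 0.83 ± 0.27, Tnf had -0.55 ± 0.32, Il18 had 0.25 ± 0.37 and Il1b had -0.16 ± 0.27. The type I interferon list had 19 of 31 genes lower (median -0.19, camera adjusted p = 0.117), with Bst2 at 0.75 ± 0.26, Rtp4 at 0.75 ± 0.32 and Ifi27l2a at 0.88 ± 0.44. The alternative activation list had 10 of 18 genes higher (median 0.21, camera adjusted p = 0.665, test pointing down), with Il1rn at -0.57 ± 0.34, Tgfbr2 at -0.42 ± 0.34 and Chil3 at -0.60 ± 0.49.

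Among genes linked to Alzheimer's disease, the list of mouse orthologs of risk genes had 18 of 30 genes lower (median -0.31, camera adjusted p = 0.315), and Apoe alone passed over the list, with Ms4a4a at 0.98 ± 0.34 and Tmem106b at -0.82 ± 0.30. The amyloid processing and clearance list had 13 of 18 genes lower (median -0.22, camera adjusted p = 0.488), with Sorl1 at -0.83 ± 0.31, the sheddase Adam17 at -0.94 ± 0.44 and Apoe again the gene that passed over the list alone. App had a log2 change of -0.21 ± 0.25 and Mapt of 1.90 ± 0.56. Mapt alone passed over the transgene ortholog list (camera adjusted p = 0.953, with median and mean differing in sign), and App and Mapt are uncertain because reads from the human transgenes were not separated here. Mapt ranked the libraries in the same order as Meg3 and Snhg11 of the neuron list, while Slc17a7 differed among the isotype libraries. Its rise may therefore not be separate from that of the neuron list.

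The remaining lists did not pass with all libraries. Endothelial and mural genes had 12 of 17 higher (median 0.36, camera adjusted p = 0.0823; past the threshold without isotype 1 or anti-NK1.1 3, camera adjusted p = 0.0417 and 0.0157), with Vtn at 1.71 ± 0.32, passing over the list alone, Ly6c1 at 1.70 ± 0.55 and Cldn5 at 2.48 ± 0.95. B cell genes were split 5 to 5 (camera adjusted p = 0.318), with Cd79b at 0.66 ± 0.28 and Jchain at 0.57 ± 0.29. Immediate early genes, which respond to tissue dissociation, had 16 of 29 lower (camera adjusted p = 0.488), and the list passed as lower with the length and GC correction (median -0.36, camera adjusted p = 0.0263) and without anti-NK1.1 3 (median -0.34, camera adjusted p = 0.0102). Among them were Egr2 at -1.65 ± 0.44, Klf6 at -0.75 ± 0.40 and Zfp36l1 at 0.70 ± 0.28. Glycolysis and hypoxia genes were split 11 to 11 (camera adjusted p = 0.583), with Pfkl at 0.41 ± 0.22 and Pfkfb3 at -0.43 ± 0.27. Unfolded protein genes had 15 of 22 lower (camera adjusted p = 0.597), with Hsp90aa1 at -0.66 ± 0.40, Hsp90b1 at -0.75 ± 0.47 and Sdf2l1 at 0.37 ± 0.22. Cholesterol and lipid genes had 12 of 27 lower (camera adjusted p = 0.714; the median lay above 0 and the mean below), with Fasn at -1.16 ± 0.45, Abca1 at -0.90 ± 0.54 and Soat1 at -0.46 ± 0.29. The sex-linked list (camera adjusted p = 0.317) had Tsix at -0.49 ± 0.30, Xist at -0.33 ± 0.29 and Eif2s3y at -0.92 ± 1.97. Eif2s3y, on the Y chromosome, had 0, 46 and 153 counts in isotype libraries 1 to 3 and 0, 88 and 7 in anti-NK1.1 libraries 1 to 3. It thus differed between libraries within each group. Erythroid genes had 2 tested members, too few for the list test, with Alas2 at 2.17 ± 1.13, and no mitochondrially encoded gene had a row in the table used.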

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

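Across 25 alternatives with a gene count, 20 also called 0 genes, while DESeq2 called 132, quantile normalization 2, sample weights 4 (both limma-voom), and the length and GC correction without anti-NK1.1 replicate 2 called 2. Among the 20, the thresholds of adjusted p under 0.10 and of an absolute log2 change of at least 1 reused the main fit. Its smallest edgeR adjusted p of 0.296 fixed their count at 0, so they add no evidence. With each library left out the count was 0 to 129, the latter without anti-NK1.1 replicate 2, whose long transcripts were better represented than those of the other anti-NK1.1 libraries. Of 24 alternatives with a list count, an estimated correlation gave 0 and fry 1, and the others 8 to 13 (8 to 13 with each library left out). Of the 12 lists past the threshold, neurons, oligodendrocyte lineage, proliferation and NK cells kept their call in all 22 alternatives with the preset correlation, with medians from 0.84 to 2.02, 0.78 to 1.56, -1.42 to -0.49 and -1.81 to -0.44. The call was kept by astrocytes, border macrophages, antigen presentation, oxidative phosphorylation and monocytes with neutrophils in 20, ribosomal proteins in 15, interferon gamma in 14 and T cells in 11. Of the lists not past the threshold, immediate early passed in 4 alternatives, type I interferon in 3, and endothelial, inflammatory cytokine and homeostatic lists in 2 each, and phagocytosis in 1. Of 100 named genes, 82 had the same sign in every fit. The replicate block gave 0 genes and 11 lists, without interferon gamma (camera adjusted p = 0.118). The block is a formal check, since libraries of the same number did not pair (correlations of 0.0525, 0.0301 and -0.00377). Each reversal follows as a log2 change, a median for lists, and for none was the cause tested. With a pseudocount of 0.1 the transgene list was -0.26, with no filter it was -0.22, and at a mean CPM of at least 5 alternative activation was 0.12, cholesterol 0.0690 and stress 0.00915. Quantile normalization gave cholesterol 0.0502 and the transgene list -0.27. The length and GC correction gave Rps15 -0.0569, Sdf2l1 -0.0695, App 0.0707 and cholesterol 0.13, with the replicate block Rps15 -0.0529, Sdf2l1 -0.0602, App 0.0779 and cholesterol 0.0297, and without anti-NK1.1 replicate 2 Ndufa13 -0.0337, Rps15 -0.12, Sdf2l1 -0.0840, Soat1 0.15 and App 0.11. The neutrophil covariate gave Il18 -0.0946, complement 0.0584, immediate early 0.10, stress -0.0315 and the transgene list -0.43. Without anti-NK1.1 1 and 3, which leaves a lone anti-NK1.1 library assumed to vary like the others, Ifi27l2a was -0.22, Rps19 -0.0225, Rps15 -0.0313, Hsp90aa1 0.0846, Tsix 0.0275, Sdf2l1 -0.0107, Hsp90b1 0.21, Cx3cr1 0.25, B2m -0.15, Trem2 -0.18, Tgfbr2 0.15, Xist 0.0446, App 0.22 and Eif2s3y 0.50, and the lists were amyloid 0.00227, alternative activation 0.12, cholesterol 0.0903, disease-associated 0.0701, homeostatic 0.0934, sex-linked 0.0361, stress 0.20 and ribosomal -0.22. With each library left out in turn, Eif2s3y ranged from -3.67 to 0.42, Il1b from -0.31 to 0.0828, alternative activation from -0.22 to 0.27, complement from -0.12 to 0.13, immediate early from -0.34 to 0.0759, stress from -0.15 to 0.0636 and the transgene list from -0.49 to -0.0278. List direction is that of the camera test, so a median can keep its sign while the list reverses. Depth was not tested apart from the spread between libraries.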

Other observations

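All tests in this part were chosen after the data had been seen, except 6 whose bounds were set before their results: the length and GC tests of the 3 patterns, the test of neutrophils for the proliferation list, and both counts over other splits of the libraries.

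Neutrophil genes of early maturation took a smaller share of gene counts in every anti-NK1.1 library than in any isotype library, and those of later maturation did so in anti-NK1.1 1 and 2. The early against the later genes were not tested. Mpo, Elane, Prtn3, Ctsg and Ms4a3, made by early precursors of neutrophils, were all lower in anti-NK1.1, with a median log2 change of -1.44 (camera adjusted p = 0.00630 over 4 added lists, adjusted p = 0.442 with an estimated correlation). Mpo had 30456, 37262 and 36121 counts in the isotype libraries and 314, 8124 and 12213 in the anti-NK1.1 libraries, a log2 change of -2.0 ± 0.89 (edgeR adjusted p = 0.743). The later granule and effector genes Ltf, Camp, Ngp, Lcn2, Retnlg, Mmp8, S100a8, S100a9 and Cxcr2 were also all lower, with a median of -0.31 (camera adjusted p = 0.0114, adjusted p = 0.462 with an estimated correlation), from -0.94 for Cxcr2 and -0.91 for Ltf to -0.05 for Camp. In shares of gene counts, all 9 later genes lay below every isotype library in anti-NK1.1 1 and 2, while in anti-NK1.1 3 the 6 genes Camp, Ngp, Lcn2, Retnlg, S100a8 and S100a9 lay above every isotype library (Ngp 2.32% against at most 1.54%). The fixed monocyte and neutrophil list holds Mpo, Elane and each of these later genes, so the lists are not independent.

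Ttr, which encodes transthyretin and is abundant in the choroid plexus, was the third most abundant gene over all libraries, with 2.37%, 2.32% and 0.687% of gene counts in the isotype and 3.87%, 3.39% and 1.91% in the anti-NK1.1 libraries (log2 change 0.80 ± 0.43, edgeR adjusted p = 0.743). A list of 8 choroid plexus genes (Ttr, Enpp2, Folr1, Kl, Clic6, Kcnj13, Otx2 and Aqp1) had all 8 higher, with a median log2 change of 0.33 (camera adjusted p = 0.0822, adjusted p = 0.546 with an estimated correlation). Sftpc, the surfactant gene of alveolar cells in the lung, had 1072, 993 and 64 counts in the isotype and 0, 14 and 24 counts in the anti-NK1.1 libraries (edgeR adjusted p = 0.714). Sftpa1 had 308, 41 and 55 against 3, 50 and 0. The list of lung epithelium genes was written after Sftpc had been seen, so it is no independent test of it. Of its 6 genes 4 were tested, 3 lower and 1 higher, the latter being Napsa, the member with the most counts (0.45 ± 0.38), and the median log2 change was -2.27 (camera adjusted p = 0.0347, adjusted p = 0.347 with an estimated correlation).

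The neuron, oligodendrocyte-lineage and astrocyte lists lay higher in anti-NK1.1 libraries. A lower share of microglia in the sort would raise the markers of every other cell type alike. The neuron median lay 1.98 above that of the monocyte and neutrophil list on the log2 scale (95% interval from resampling genes 1.40 to 2.64). That interval leaves out the spread between libraries. Neutrophil transcripts also varied on their own, from 2.87% to 11.1% of gene counts in the anti-NK1.1 libraries. The test therefore cannot decide, and a lower share of microglia stays open. After the length and GC correction the neuron list had 1.09 times its median (1.63, camera adjusted p = 4.44e-08) and the oligodendrocyte-lineage list 1.05 times, which argues against that trend for these lists, while the astrocyte list had 0.732 times its median (0.51, camera adjusted p = 0.00223) and with anti-NK1.1 replicate 2 also left out no longer passed (camera adjusted p = 0.0504). Carry-over of RNA from brain tissue remains a candidate explanation: in each list the 5 most abundant members had a positive median, the lowest being 1.04, although a share of 0.831 of random draws of 5 members per list also had mostly higher genes in all 3 lists, so the test is weak. A response of the cells to NK cell depletion, such as uptake of brain material by microglia, was not tested and stays open.

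MHC class II genes, Cd74 and Apoe lay higher in anti-NK1.1 libraries. A larger share of border macrophages would bring their abundant markers along, but the 5 most abundant (F13a1, Clec12a, Stab1, Pf4 and Ms4a7) had a median log2 change of 0.29 against 1.34 ± 0.20 for Cd74, the smallest of the class II set. These 5 went both ways (SD 1.27), F13a1 and Clec12a are also expressed by monocytes, and Pf4 and Ms4a7 alone had 1.37 and 1.27, so the test decides nothing and these cells stay open as a source. After the length and GC correction the median of H2-Aa, H2-Ab1, H2-Eb1, Cd74 and Apoe was 1.07, which is 0.740 times its value of 1.45. All 5 genes stayed higher in each anti-NK1.1 library than in each isotype library. The fitted trend may thus contribute but does not account for the whole. The 5 genes were picked from these data as already not overlapping, and a length effect that the fitted trend misses was not tested. Other cells as a source of these transcripts, and carry-over of RNA from brain tissue, were not tested for these genes. Higher class II and Apoe expression in the microglia themselves after NK cell depletion was not tested.

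The proliferation list lay lower in anti-NK1.1 libraries. For a loss of neutrophils in general the values cannot decide. In anti-NK1.1 3, neutrophil transcripts took 11.1% of counts, but the list's mean log2 CPM lay at -0.41 relative to the lowest isotype library (SD of the isotype libraries 0.05). After the length and GC correction it was 4.15 against 4.31 (SD 0.06). The fit with neutrophil transcripts as a covariate left a median of -0.49 (camera adjusted p = 0.000480). The comparison of anti-NK1.1 3 rests on 1 library, while the list's mean log2 CPM was 2.09, 3.45 and 4.01 in anti-NK1.1 1 to 3. The covariate fit rests on camera with the preset correlation. The list's summed CPM in anti-NK1.1 3 was 893, within the isotype range of 870 to 925, against 321 and 472 in anti-NK1.1 1 and 2. A loss of neutrophils therefore stays open. After the length and GC correction the list had 0.967 times its median (camera adjusted p = 2.79e-08), which argues against that trend. A loss of early neutrophil precursors, which divide, stays open. Their 5 genes had a median log2 change of -1.44, lower than that of the proliferation list (difference -0.65, 95% interval from resampling genes -1.28 to -0.37). That interval leaves out the spread between libraries and treats the 5 genes as independent, although their estimated correlation was 0.99. All 5 were lower in every anti-NK1.1 library than in every isotype library as shares of gene counts, but 2 of the 5 after TMM scaling, so the answer depends on the scale. A lower rate of division in microglia or other sorted cells was not tested.

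With 6 libraries in groups of 3 there are 10 splits, too few for a share under 0.05. The count of genes changed was 0 in the real split, so all 10 splits had as many, and the highest of the others was 1. For the gene lists past the threshold the real split, with 12, was the 1 split with as many, and the highest of the others was 10. At an unadjusted p under 0.05, the real split had 950 genes, and 2 other splits had more: 1396 with isotype 1, anti-NK1.1 1 and anti-NK1.1 3 together, the libraries with the lowest trend with transcript length, and 1057 with isotype 1, isotype 3 and anti-NK1.1 2 together.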
